A study of Homo sapiens with 14 samples.

How the data were processed

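Total RNA from 7 human prostate cancer cell lines had been hybridised, after biotin labelling, to 14 single-colour oligonucleotide expression arrays. Each line was represented by 2 arrays, made per the series design from different passages in culture. Per the labels, all lines grew in DMEM with fetal bovine serum and gentamicin, RNA came from a column kit, and the labelled target was made with a commercial biotin module. The deposited values were intensities after RMA by the authors, which subtracts background, equalises the distribution of the probes between arrays and summarises each probe set by median polish. The version of RMA was not given in the sources used here. The deposited intensities were on a linear scale, read from the values themselves: they ran from 18.5 to 8654, and the array medians lay between 29.9 and 31.6. They were converted to log2 with no pseudocount before any test.

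The deposited table held 28829 probe sets. Of these, 19291 carried exactly 1 gene symbol, 1735 carried several and 7803 had no gene in the probe table. Gene identifiers of 19260 of the probe sets matched a RefSeq gene table (GRCh38.p14), which was used for names alone, and 0 symbols needed updating. For the 682 genes with several probe sets, the one with the highest mean over all arrays stood for the gene. This left 18372 genes for testing, with no filter on low intensity. Arrays give no detection counts. Intensities near the lower end are compressed toward a floor, so a fold change against a group near that floor is a low estimate. Genes are listed by the size of the change as measured, which is no ranking where a level lies near the floor. The number of arrays limits the precision.

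One model with a mean per line was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), which left 7 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p over the 18372 genes was under 0.05. All tests were two-sided. The 2 arrays of a line come from separate passages of one culture, so every p from this model measures a difference against the spread between passages, not between independently derived lines. In all, 8 pairs of lines were compared, with 1 further contrast for the difference between the effects of PDGFRα overexpression in PC3-N and in DU-145. The label of bone-metastatic potential belongs to a line, so the 4 bone-metastatic lines were compared with the 3 others on the 7 line means. The p values of that comparison measure a difference against the spread between lines. They treat the lines as independent, which they are not. Both clones come from PC3-ML, PC3-N(PDGFRα) from PC3-N and DU-145 (PDGFRα) from DU-145. Genes called in the same direction in all 4 bone-metastatic lines against PC3-N were counted beside the number expected of independent lists and beside 100 simulations of unchanged lines measured against shared controls. The comparison between the clones used 50 such simulations.

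A set of 19 gene lists with 260 different genes, 234 of them measured, was written before the data were examined, as were the groups, the comparisons, the tests and the alternatives other than those named as later additions. The lists covered interleukin-1 (IL-1) and NF-kB cytokines and targets, the androgen receptor program, neuroendocrine, epithelial, mesenchymal and basal epithelial markers, bone and osteomimicry genes, integrins, matrix proteases with plasminogen activation, and PDGF ligands and receptors. Others covered growth factor immediate early and MAPK output genes, interferon-stimulated genes, cell cycle, cholesterol synthesis, hypoxia, and amino acid and endoplasmic reticulum (ER) stress genes, fibroblast and stromal markers, leukocyte and endothelial markers, and genes deleted in PC3 cells. The last was too short for a test, which needed at least 3 measured genes. The other 18 were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 180 pairs of list and comparison. Beside it stood camera with an estimated correlation and fry, which tests a list alone. Counts of members are given over all genes tested and adjusted over the list alone.

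Genes were named by a rule. In PC3-ML against PC3-N and in both comparisons of overexpression, the 10 largest rises and 10 largest falls were named among called genes whose arrays did not overlap between the lines. In other comparisons the 5 largest of each were named, from each list up to 4 members per comparison, and from the overlap up to 15 genes per direction. In the comparison of bone-metastatic lines, where fewer passed, the 5 genes of each direction with the smallest p were given as values. PDGFRA, IL1B, CXCL6 and ELMO1 were always named. The last 3 were known from the study's publication and are not independent evidence. IL1B and CXCL6 are members of the IL-1 and NF-kB list, so the tests of that list are not independent of the publication either. Small RNAs, Y-linked genes and unnamed loci were not named. One gene lower in PC3-ML than in PC3-N is not reported here. Other probe sets of a named gene are mentioned where they differed.

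The procedure was tested on simulated data built like PC3-ML against PC3-N, with 200 changed genes among 18372 in each of 10 runs. It recovered 70% of changes of 0.5 log2, 97.9% of changes of 1 and 99.9% of changes of 2, with 5.64% false calls. These rates hold for the noise as simulated. They cannot show what passage differences shared by many genes do to the calls in the real arrays. There PC3-ML against PC3-N gave 64 genes, 12 without PC3-N replicate 1 and 170 without PC3-N replicate 2. For the bone-metastatic line means the procedure recovered 85.2% of changes of 1 log2 and 96.3% of changes of 2. That simulation used genes drawn at random and independent lines. This does not describe genes that vary more between lines. The recovery also depends on the 200 changed genes, which ease the adjusted threshold. In the real line means 0 genes were called, so differences of 3.00 for CXCL6 and 3.79 for IL1B were not called either.

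Alternatives were a replicate block, quantile normalization, median centring, a filter on dim probes, every probe tested on its own, a prior variance with an intensity trend, a minimum change of 2-fold, a fit of the 2 lines alone, and leaving out each array in turn. For the bone-metastatic lines they were also the line as a random block, the cell background as a covariate, PC3 lines alone, and leaving out each line or passage number. A count was taken as moved when it changed by more than 1.5 times. For comparisons that DU-145 is no part of, a fit without DU-145 replicate 1 was added after seeing the data, as was the contrast between the clones, before its own result. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without exactly 1 symbol were left out of the gene tests and counted apart.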

Results

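The series profiled 7 human prostate cancer cell lines, 5 of PC3 and 2 of DU-145 background, with 2 arrays per line. PC3-ML and PC3-N are sublines of PC3. PC3-ML (Clone 1) and PC3-ML (Clone 3) are progeny of single PC3-ML cells, here called Clone 1 and Clone 3. PC3-N(PDGFRα) and DU-145 (PDGFRα) overexpress the platelet-derived growth factor receptor alpha, encoded by PDGFRA. The labels call 4 lines bone metastatic (PC3-ML, Clone 1, Clone 3 and PC3-N(PDGFRα); 8 arrays) and 3 not (PC3-N, DU-145 and DU-145 (PDGFRα); 6 arrays). The series title asks how expression differs between these groups. The 2 arrays of a line correlated at r of 0.989 to 0.996 across genes, lines of PC3 background at 0.972 to 0.993 and arrays of the 2 backgrounds at 0.926 to 0.948, with genes not being independent replicates. PC3-N replicate 2 was closer to PC3-ML replicate 2 (r = 0.9935) than to its own other passage (0.9925), and DU-145 replicate 2 closer to DU-145 (PDGFRα) replicate 1 (0.9905) than to its own (0.9891). Intensities below are the mean ± SD of 2 passages.

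PDGFRA intensity was 833.9 ± 23.3 in PC3-N(PDGFRα) against 106.4 ± 4.32 in PC3-N, and 110.9 ± 26.4 in DU-145 (PDGFRα) against 26.9 ± 1.92 in DU-145. It was 129.8 ± 36.3 in PC3-ML, 127.8 ± 3.27 in Clone 3 and 28.8 ± 3.21 in Clone 1, so 1 of the 4 bone-metastatic lines had the PDGFRA level of unmodified DU-145. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, read 1085 ± 26.2 in PC3-N(PDGFRα), 736.9 ± 47.0 in Clone 1, 511.2 ± 71.0 in Clone 3 and 261.0 ± 4.51 in PC3-ML. Its intensity was 83.5 ± 17.0 in PC3-N, 28.5 ± 1.75 in DU-145 and 30.1 ± 2.76 in DU-145 (PDGFRα). CXCL6, a chemokine that attracts neutrophils, was at 350.5 ± 29.0 in Clone 1, 348.8 ± 36.7 in Clone 3, 230.1 ± 28.7 in PC3-ML and 173.6 ± 2.58 in PC3-N(PDGFRα), against 45.4 ± 0.656 in PC3-N, 27.3 ± 3.42 in DU-145 and 29.2 ± 2.41 in DU-145 (PDGFRα). ELMO1, a gene of cell engulfment and motility, stayed near the floor in every line, between 21.1 and 22.6. CTNNA1, the alpha-catenin gene known to be deleted in PC3 cells, lay between 23.1 and 24.0 in the 5 PC3 lines and at 219.7 ± 88.5 in DU-145 and 178.5 ± 57.3 in DU-145 (PDGFRα).

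**Figure D1:**
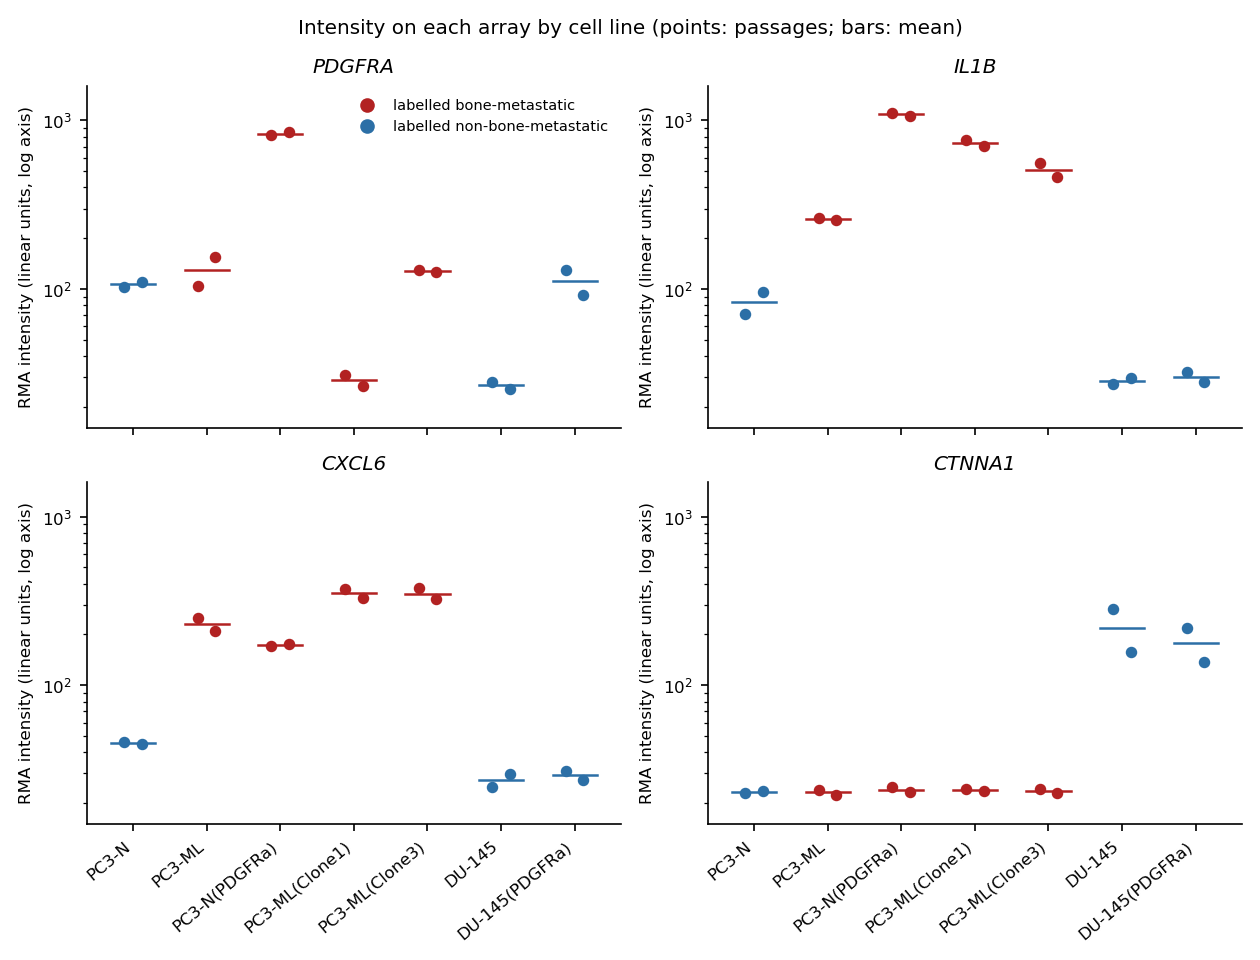
RMA intensity (log axis) of PDGFRA, IL1B, CXCL6 and CTNNA1 in each array by line; points are the 2 passages, bars their mean, red lines are labelled bone metastatic and blue ones not. Line means of IL1B ran from 261.0 to 1085 in the 4 bone-metastatic lines and from 28.5 to 83.5 in the other 3, whereas PDGFRA in Clone 1 was 28.8.

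PC3-ML was compared with PC3-N to ask how a bone-metastatic subline differs from one labelled as not bone metastatic, of the same origin. Among its largest rises were CXCL6, at 230.1 in PC3-ML and 45.4 in PC3-N (log2 change 2.33, SE 0.12, adjusted p = 3.2e-05), and ESM1, a secreted proteoglycan (2.30, from 25.5 to 124.7). The ESM1 value in PC3-N lies near the floor, so its change is a low estimate and the 2 are not ranked. Others were CYB5R2, a cytochrome b5 reductase (2.24), EPB41L3, a membrane skeleton protein (2.02), and ZFPM2, a cofactor of GATA factors (1.94). PI3, an elastase inhibitor, rose by 1.81, TIMP3, an inhibitor of metalloproteinases, by 1.75, IL1B by 1.66 (SE 0.14, adjusted p = 0.00069), the homeobox gene HOXB9 by 1.37 and BEX1 by 1.2. The largest measured fall was in RGS4, a brake on G-protein signalling, from 110.1 to 32.1 (log2 change −1.75, SE 0.17, adjusted p = 0.0023). ZNF667-AS1 (−1.31), the simple epithelial keratin KRT8 (−1.08), TENT5C (−0.89) and CABLES1 (−0.85) followed, then TAF7 (−0.71), PRICKLE1 (−0.69), KLHL4 (−0.62) and the kinase gene PLK2 (−0.60). A second TIMP3 probe set gave 0.37 with an adjusted p of 0.14. ELMO1 (0.02, adjusted p = 0.976) and PDGFRA (0.26, adjusted p = 0.766) were not called.

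Among the gene groups, the IL-1 and NF-kB cytokines and targets were higher in PC3-ML as a list (camera adjusted p = 2.09e-10, and adjusted p = 0.294 with an estimated correlation). Of its 21 measured members 4 rose, 0 fell and 17 were not called, and 8 rose when adjusted over the list alone. The 4 were CXCL6, IL1B, the chemokine CXCL1 (1.15) and NFKBIA (1.07), the inhibitor of NF-kB that NF-kB itself induces. The chemokine CXCL8 had a change of 1.59 with an adjusted p of 0.0504. Hypoxia genes were lower as a list (adjusted p = 0.0353, and adjusted p = 0.720 with an estimated correlation), with 0 of 14 called, 5 at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone; NDRG1 had a log2 change of −1.27. Amino acid and ER stress genes were also lower (adjusted p = 0.0111, and adjusted p = 0.759 with an estimated correlation), with 0 of 14 called, 3 at an unadjusted p under 0.05, 2 lower when adjusted over the list alone, and SLC7A11, the cystine transporter, at −1.26. Fry did not call these 2 lower lists, with an adjusted p of 0.199 for hypoxia and 0.258 for amino acid and ER stress genes. In all, limma called 64 genes, 40 higher and 24 lower, 16 of them changed at least 2-fold. The count was 15 without PC3-ML replicate 1, 12 without PC3-N replicate 1 and 170 without PC3-N replicate 2. More genes were lower than higher in the last of these (53 higher, 117 lower), without PC3-ML replicate 2 (27 and 32) and with a filter on dim probes (51 and 52). With a replicate block, CABLES1, PRICKLE1, ZNF667-AS1 and CXCL1 lost their call. Of the 20 genes with the largest changes, CXCL6, ESM1, CYB5R2, EPB41L3, ZFPM2, TIMP3, IL1B, HOXB9 and RGS4 kept their call without any 1 array; the other 11 lost it without PC3-ML replicate 1 (adjusted p up to 0.355) and without PC3-N replicate 1 (up to 0.238), as did CXCL1 (adjusted p = 0.248 and 0.201) and NFKBIA (0.0649 and 0.0694).

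**Figure D2:**
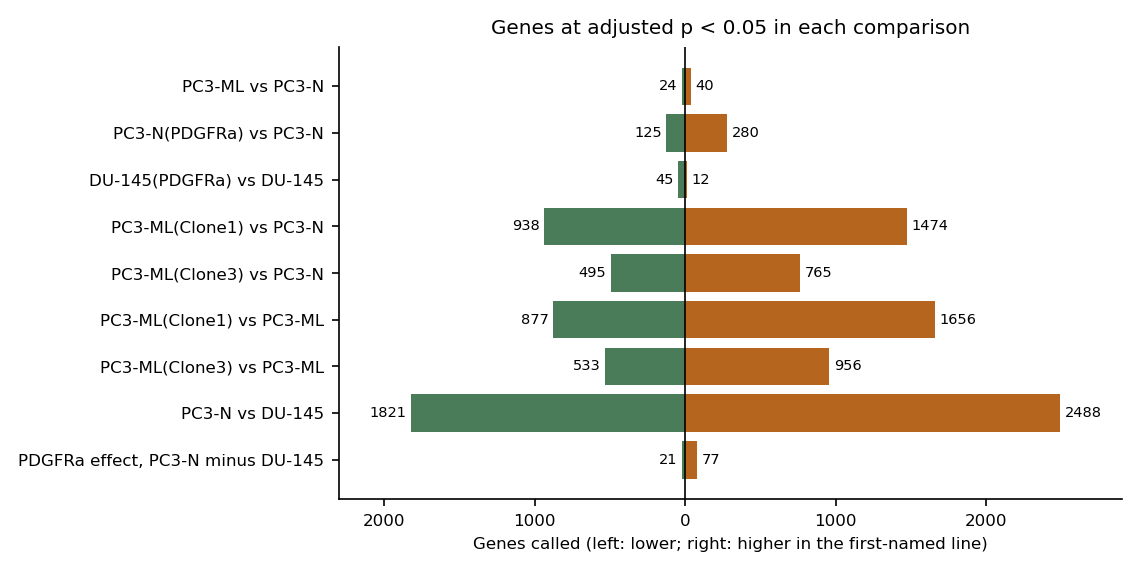
Number of genes called by limma (adjusted p under 0.05 of 18372 genes) as higher or lower in the first line than in the second, for 9 comparisons. Counts run from 57 for PDGFRα overexpression in DU-145 to 4309 for PC3-N against DU-145.

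PC3-N(PDGFRα), labelled bone metastatic, was compared with unmodified PC3-N, labelled as not, to ask what differs in cells that overexpress the receptor. The series held no control line handled the same way without the receptor, in PC3-N or in DU-145. A difference from the unmodified line therefore cannot be assigned to the receptor alone. The effect of overexpression, or a response to it, means this difference between lines throughout. The largest measured rises were in IL1B and the receptor itself. IL1B rose 13.1-fold (log2 change 3.72, SE 0.14, adjusted p = 2.6e-06) and PDGFRA 7.84-fold (2.97, SE 0.19, adjusted p = 8.0e-05). PI3 (2.14), ESM1 (2.09, a low estimate as before), the lysosomal enzyme gene GALC (2.01), MLLT11 (1.99), CXCL6 (1.93), the actin-bundling LCP1 (1.76), the cystatin CST1 (1.70) and EPB41L3 (1.69) rose as well. The largest measured falls were in DPP4, a cell surface peptidase (−2.13, SE 0.33, adjusted p = 0.014), the cyclin gene CCNA1 (−2.12, SE 0.14, adjusted p = 8.0e-05), the urea transporter SLC14A1 (−1.76) and the tetraspanin TSPAN8 (−1.72). TFF1, a trefoil peptide, fell by 1.69, NT5E, an ectonucleotidase, by 1.65, PLK2 by 1.55, RGS4 by 1.5, PLAT, the tissue plasminogen activator, by 1.45 and ZNF717 by 1.41. ELMO1 was not called (0.10, adjusted p = 0.477).

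The IL-1 and NF-kB list was higher here too (adjusted p = 1.06e-07, and adjusted p = 0.294 with an estimated correlation): 6 of 21 members rose, 0 fell and 15 were not called, and 8 rose when adjusted over the list alone. Beside IL1B and CXCL6, CXCL2 rose by 1.42 and CXCL8 by 1.34. Cell cycle genes were higher as a list (adjusted p = 0.0356, and adjusted p = 0.759 with an estimated correlation), although 1 of 17, the mitotic kinase gene AURKA (0.40), was called and 5 rose and 1 fell over the list alone; with quantile normalization the adjusted p was 0.144. Amino acid and ER stress genes were lower (adjusted p = 0.00851, and adjusted p = 0.759 with an estimated correlation) with 0 of 14 called, either way of adjusting, and 4 at an unadjusted p under 0.05. Fry called neither of the last 2 lists, with an adjusted p of 0.111 for cell cycle and 0.213 for amino acid and ER stress genes. Among 14 matrix protease and plasminogen genes 0 rose and 3 fell: PLAT, the collagenase MMP13 (−1.09) and TIMP3 (−0.78), for which a second probe set gave −0.22 with an adjusted p of 0.28. Among 12 integrins ITGB3 rose by 0.55 and ITGB5 fell by 0.40, the latter named after its value was seen. The stromal marker PDPN (0.70) and the macrophage marker CD68 (0.66) rose, 1 member of each of those lists. In all 405 genes were called, 280 higher and 125 lower, 44 of them at least 2-fold; the count was 118 without PC3-N replicate 1, 71 without PC3-N(PDGFRα) replicate 1 and 158 without its replicate 2. CST1, DPP4, SLC14A1, TFF1, NT5E and ZNF717 each lost the call without at least 1 of these 3 arrays (adjusted p up to 0.181), as did CXCL2, CXCL8, AURKA, MMP13, ITGB3, PDPN and CD68 (up to 0.243; with a replicate block CXCL8 and MMP13 lost it too, up to 0.0684), while IL1B, PDGFRA, PI3, ESM1, GALC, MLLT11, CXCL6, LCP1, EPB41L3, CCNA1, TSPAN8, PLK2, RGS4, PLAT and TIMP3 kept it.

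In DU-145, where both lines are labelled as not bone metastatic, PDGFRα overexpression raised PDGFRA 4.07-fold (log2 change 2.03, SE 0.19, adjusted p = 0.0045), a low estimate from 26.9. The other named rises were the Mediator gene MED7 (0.70), the spindle gene ASPM (0.70), the inositol pyrophosphate kinase PPIP5K2 (0.57), GLTPD2 (0.49), LKAAEAR1 (0.42), LCMT1P1 (0.42), OBI1 (0.35) and the caspase gene CASP6 (0.35). Small nucleolar RNA genes or pseudogenes, which were not named, made up the 2 other rises of at least 2-fold. Named falls were in TXNIP, a thioredoxin inhibitor (−1.55, SE 0.20, adjusted p = 0.030), MAL2, a protein of apical transport (−1.34), TGFBI, a matrix protein induced by TGF-beta (−1.03, SE 0.08, adjusted p = 0.0021) and CCDC88C (−0.97, SE 0.06, adjusted p = 0.00035). CDCP1 (−0.87), CT83 (−0.85), MRPL37 (−0.85), the iron-responsive aconitase ACO1 (−0.79), S100A2 (−0.78) and RRAGD (−0.78) completed the 10. IL1B (0.08, adjusted p = 0.874), CXCL6 (0.10, adjusted p = 0.785) and ELMO1 (−0.03, adjusted p = 0.890) were not called. A second CCDC88C probe set gave −0.37 and was not called (limma adjusted p = 0.46).

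In DU-145 limma called 0 of the 21 IL-1 and NF-kB members, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. For the list, camera gave an adjusted p of 0.256 and fry one of 0.481. Hypoxia genes were lower as a list (adjusted p = 0.00582, and adjusted p = 0.592 with an estimated correlation), with 0 of 14 called, 6 at an unadjusted p under 0.05 and 3 lower over the list alone. Fry did not call the hypoxia list (adjusted p = 0.111). Of 14 amino acid and ER stress genes 1 fell, the lipoprotein receptor gene VLDLR (−0.64). In all 57 genes were called, 12 higher and 45 lower, 6 at least 2-fold; with quantile normalization the split was 29 higher and 51 lower. With a replicate block 10 were called, 3 higher and 7 lower; of the called genes named here PDGFRA, TGFBI, CCDC88C, CT83 and S100A2 kept their call, and the others lost it (adjusted p up to 0.0692). The count was 20 without DU-145 replicate 1, 418 without its replicate 2, 31 without DU-145 (PDGFRα) replicate 1 (16 higher, 15 lower) and 15 without its replicate 2 (9 higher, 6 lower). PDGFRA, TGFBI and CCDC88C kept their call without any 1 array, and the other 16 of the 19 named genes, with VLDLR, lost it without at least 1 of them (adjusted p up to 0.167).

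The difference between these effects was tested directly, since the receptor was followed by a bone-metastatic label in PC3-N alone. IL1B responded more in PC3-N (log2 difference 3.64, SE 0.19, adjusted p = 9.0e-05). PI3 (2.96), GALC (2.33), MLLT11 (2.27), ESM1 (2.17) and CXCL6 (1.83) also had higher responses in PC3-N. CCNA1 (−1.91), TSPAN8 (−1.88), PLK2 (−1.67), PLAT (−1.62) and RGS4 (−1.60) had lower ones. In both DU-145 lines IL1B, ESM1, CXCL6, CCNA1, TSPAN8, PLAT and RGS4 lay between 24.3 and 43.9, near the floor, where a response is compressed or cannot be seen, so the size and order of their differences are uncertain. The rise of PDGFRA itself differed by 0.95 with an adjusted p of 0.181, and ELMO1 by 0.13 with one of 0.552, so neither was shown to differ. The IL-1 and NF-kB list responded more in PC3-N (adjusted p = 2.83e-08, and adjusted p = 0.294 with an estimated correlation; mean difference 0.64). Of its 21 members 3 were called, IL1B, CXCL6 and NFKBIA (1.15), and 9 over the list alone, all higher. The urokinase gene PLAU (1.56), ITGB3 (0.78) and CD68 (1.01) were higher and TIMP3 (−0.74) lower. NFKBIA and TIMP3 were named here after their values were seen. In all 98 genes were called, 77 higher and 21 lower, 34 at least 2-fold. The count was 39 without PC3-N replicate 1, 153 without its replicate 2 (86 higher, 67 lower), 26 and 44 without PC3-N(PDGFRα) replicates 1 and 2, 58 and 249 without DU-145 replicates 1 and 2, and 63 and 45 without DU-145 (PDGFRα) replicates 1 and 2. MLLT11, PLAT and RGS4 lost their call in some of these (adjusted p up to 0.0964), as did PLAU, ITGB3 and CD68 (up to 0.147; PLAU also with a replicate block, 0.0692), and the other 7 leading genes and CXCL6 kept it.

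**Figure D3:**
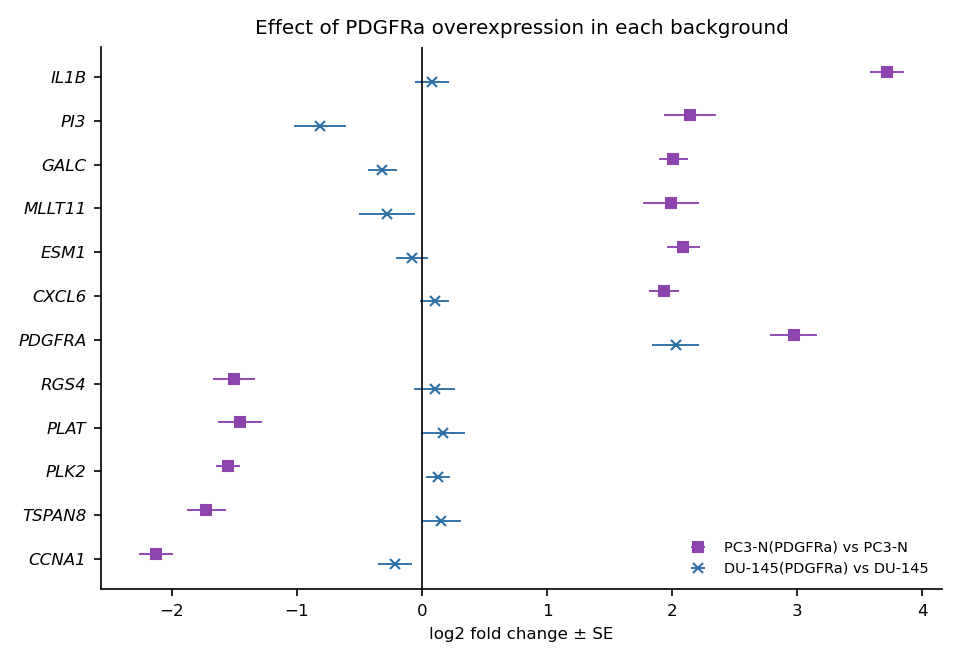
Log2 fold change ± SE of PDGFRα overexpression in PC3-N and in DU-145 for 12 genes, 2 arrays per line. IL1B rose by 3.72 in PC3-N against a value of 0.08 in DU-145, and PDGFRA rose by 2.97 and 2.03.

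Both clones were compared with PC3-N as further bone-metastatic lines of the same background. In Clone 1 IL1B rose 8.91-fold (log2 change 3.16, SE 0.14, adjusted p = 4.2e-06), with CXCL6 (2.95), LCP1 (2.70), ESM1 (2.54) and IL13RA2, a decoy receptor of interleukin-13 (2.43). The largest measured falls were in PLAT (−3.45, SE 0.18, adjusted p = 7.3e-06), ZNF667-AS1 (−3.15), TSPAN8 (−3.13), TFF1 (−2.24) and PLK2 (−2.15), and PDGFRA fell by 1.89 (SE 0.19, adjusted p = 0.00027). In Clone 3 the largest measured rise was in SERPINB3, a serpin family gene of squamous epithelia (4.91, from 22.4, near the floor, SE 0.11, adjusted p = 2.4e-08). LCN2, a lipocalin that binds iron-carrying siderophores (4.21), FEZ1 (3.50), CYB5R2 (3.04) and CXCL6 (2.94) followed, and IL1B rose by 2.62. The surface glycoprotein CD24 (−3.00), LCP1 (−2.26), RGS4 (−1.91), the vascular endothelial growth factor receptor KDR (−1.59) and the keratin KRT75 (−1.44) fell in Clone 3, where PDGFRA was not called (0.27, adjusted p = 0.544). LCP1 was thus called in opposite directions in the 2 clones. ELMO1 stayed at the floor in both.

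The IL-1 and NF-kB list was higher in Clone 1 (adjusted p = 0.00179, and adjusted p = 0.592 with an estimated correlation; 7 of 21 rose, 0 fell, the same numbers over the list alone) and in Clone 3 (adjusted p = 5.26e-06, and adjusted p = 0.438 with an estimated correlation; 8 rose, 0 fell, 9 over the list alone). Cell cycle genes were higher in Clone 1 (adjusted p = 5.26e-06, and adjusted p = 0.481 with an estimated correlation): 8 of 17 rose, 11 over the list alone, led by BUB1 (0.96), CDK1 (0.84), MCM3 (0.80) and TOP2A (0.75). In Clone 3 AURKA (0.58) and TOP2A (0.52) rose, 2 of 17 (5 rose and 1 fell over the list alone; adjusted p = 0.0356, adjusted p = 0.759 with an estimated correlation, and 0.291 with quantile normalization). Fry did not call the cell cycle list in Clone 3 (adjusted p = 0.0578). Growth factor and MAPK output genes, many of them feedback regulators of the pathway, were lower in Clone 1 (adjusted p = 0.0111, and adjusted p = 0.454 with an estimated correlation): 8 of 19 fell, 9 over the list alone, including DUSP4 (−0.73), SPRY2 (−0.65) and DUSP6 (−0.61). In Clone 3 that list split, with 3 risen, PHLDA1 (0.74) and MYC (0.66) among them, and 3 fallen, ETV5 (−0.59) among them. Of 12 integrins 4 rose in Clone 1, ITGB3 the most (1.00), and 1 fell, ITGB8 (−1.09), while 3 rose in Clone 3, ITGAV the most (0.66). The bone genes RUNX2 (0.58) and DKK1 (0.48) rose in Clone 3, 2 of 15, whereas NOG of the same list fell in Clone 1 (−0.58). The epithelial adhesion gene EPCAM rose in Clone 1 (1.52), 1 of 15 epithelial markers. Members of the cell type lists moved in Clone 1 as well: PDPN (1.14) and the endothelial PECAM1 (0.87) rose, and KDR (−1.33) and LYZ (−0.51) fell.

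Against PC3-N, 2412 genes were called in Clone 1 (1474 higher, 938 lower, 214 at least 2-fold; 1253 and 1017 with quantile normalization, 1757 and 680 with median centring) and 1260 in Clone 3 (765 higher, 495 lower, 88 at least 2-fold; 611 and 563, and 927 and 392). Without Clone 1 replicate 1 or 2 the first count was 1514 or 1325, and without PC3-N replicate 2 or Clone 3 replicate 1 or 2 the second was 787, 606 or 604. All 10 leading genes of Clone 1 and 9 of 10 of Clone 3 kept their call without any 1 array. The exception, KRT75, lost it without PC3-N replicate 1 or either Clone 3 array (adjusted p up to 0.199). Of the list members named, SPRY2 lost its call without any of the 4 arrays (adjusted p up to 0.223), ITGB8 without PC3-N replicate 1 (0.0824) or Clone 1 replicate 1 (0.101), and KDR in Clone 1 without its replicate 1 (0.0501). PECAM1 lost it without any of the 4 arrays (up to 0.223) and with a replicate block (0.0508), and LYZ without PC3-N replicate 1, DU-145 replicate 1 or either Clone 1 array (up to 0.195). In Clone 3, TOP2A lost it without PC3-N replicate 1 (0.0558) or Clone 3 replicate 1 (0.0600), ITGAV without PC3-N replicate 2 or either Clone 3 array (up to 0.0649), RUNX2 without Clone 3 replicate 2 (0.0518) and DKK1 without its replicate 1 (0.0775).

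Each clone was also compared with PC3-ML, the line it came from. In Clone 1 the lysophosphatidic acid receptor LPAR3 (2.33, SE 0.15, adjusted p = 3.2e-05), the glycolytic enzyme gene ENO1 (2.28), KRT18 (2.20), LMAN2 (2.15) and KRT7 (2.06) rose most. TSPAN8 (−3.15), PLAT (−2.72), TIMP3 (−2.55), ZFPM2 (−2.48) and the fatty acid carrier FABP4 (−2.43) fell most, and PDGFRA fell by 2.15. In Clone 3 SERPINB3 (4.5, SE 0.11, adjusted p = 5.6e-08), LCN2 (3.49), FEZ1 (2.81), SERPINB4 (2.32) and the phospholipase PLA2G4A (2.24) rose most. LCP1 (−3.02), EPB41L3 (−2.96), ZFPM2 (−2.47), ESM1 (−2.45) and TIMP3 (−2.22) fell most there, and PDGFRA was not called (0.01, adjusted p = 0.992). IL1B was above PC3-ML in both (1.5 and 0.96), as was CXCL6 (0.61 and 0.60; with quantile normalization not called, adjusted p = 0.0552 and 0.0669). Other probe sets moved less: 0.53 for KRT18 in Clone 1, and −0.70 and −0.53 for TIMP3 in Clone 1 and Clone 3.

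The epithelial markers were higher in Clone 1 than in PC3-ML as a list (adjusted p = 0.0200, and adjusted p = 0.665 with an estimated correlation), with KRT18, EPCAM (1.81) and KRT8 (0.92) risen of 15, the same 3 over the list alone. Cell cycle genes were higher (adjusted p = 0.00118, and adjusted p = 0.592 with an estimated correlation; 8 of 17 rose, 0 fell, 9 and 1 over the list alone) and MAPK output genes lower (adjusted p = 0.0356, and adjusted p = 0.558 with an estimated correlation; 0 of 19 rose, 5 fell, 5 over the list alone). Integrins were higher in Clone 1 (adjusted p = 0.0388, and adjusted p = 0.704 with an estimated correlation) with ITGB3 (0.86), ITGAV (0.65) and ITGA5 (0.63) risen and ITGB1 (−0.38) fallen of 12, 5 and 1 over the list alone. The adjusted p by camera for integrins was 0.0705 with quantile normalization and 0.06 with a replicate block. No list passed in Clone 3, where fibronectin, FN1, rose by 1.39. The IL-1 and NF-kB list did not pass against PC3-ML (adjusted p = 0.893 in Clone 1 and 0.690 in Clone 3). IL1B, CXCL6 and ICAM1 (0.49 and 0.47) were risen in both, CCL2 (−0.40 and −0.42) was fallen in both and CXCL5 (−0.40) in Clone 1, the last 2 named after their values were seen. BEX1 fell in both clones (−1.80 and −1.62). Limma called 2533 genes in Clone 1 (1656 higher, 877 lower, 230 at least 2-fold; 1250 and 1087 with quantile normalization, 2029 and 633 with median centring) and 1489 in Clone 3 (956 higher, 533 lower, 115 at least 2-fold; 735 and 663 with quantile normalization, 1166 and 414 with median centring). The first count was 1213 without PC3-ML replicate 1 and 1632 or 1256 without Clone 1 replicate 1 or 2, and the second 431 without PC3-ML replicate 1 and 574 or 739 without Clone 3 replicate 1 or 2. KRT18 lost its call without PC3-ML replicate 1 or Clone 1 replicate 2 (adjusted p up to 0.0703), while the other 19 leading genes, IL1B, EPCAM, KRT8, ITGB3 and BEX1 kept theirs without any 1 array. CXCL6 lost its call without PC3-ML replicate 2 or replicate 1 of the clone, ITGAV and FN1 without PC3-ML replicate 1, ITGA5 without either PC3-ML array or Clone 1 replicate 2, ITGB1 without any of the 4, and ICAM1 without PC3-ML replicate 1 and 1 or both clone arrays (all at an adjusted p up to 0.258).

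In all 4 bone-metastatic lines against PC3-N, 19 genes were called in the same direction, 14 higher and 5 lower. The 14 were IL1B, CXCL6, CXCL1, NFKBIA, PI3, the protease inhibitor SLPI, CYB5R2, BICC1, CCDC88C, CEP170, FAM111B, MAP4K5, SMIM30 and TRNT1, so 4 belong to the IL-1 and NF-kB list. The 5 were RGS4, TENT5C, DLG2, RSRC1 and the ephrin receptor gene EPHA4. The smallest of the 4 rises was 1.93 for CXCL6, 1.81 for PI3, 1.66 for IL1B, 1.00 for NFKBIA and 0.95 for CXCL1, and RGS4 fell by 1.5 to 1.91. Of the 14, 9 were higher in every bone-metastatic line than in all 3 other lines; NFKBIA was among the 5 that were not. Of the 5 lower genes only RSRC1 lay below all 3 other lines. In DU-145 (PDGFRα) against DU-145, 1 of the 19 was called, CCDC88C, and in the opposite direction (−0.97). A second CCDC88C probe set gave values of −0.40 to −0.06 in the 4 lines, none called. Independent lists would share 0.00204 and 0.000225 genes, which leaves out the shared arrays and the shared origin of the lines. In 100 simulations of lines with no effect at all, at most 0 were shared in either direction. Without changed genes hardly any are called, so a value near 0 was bound to follow. It cannot show what the shared arrays contribute. PC3-N had only 2 arrays, which all 4 comparisons share, so part of the overlap may come from them. Clone 1 and Clone 3 come from PC3-ML, so part may also come from this shared origin. The count was 6 without PC3-ML replicate 1, 4 and 57 without PC3-N replicates 1 and 2, and 8 and 11 without PC3-N(PDGFRα) replicates 1 and 2. The 57 were 12 higher and 45 lower, and 10 of the 19 were among them. IL1B, CXCL6 and RGS4 remained in the 18 settings tried, which hold no fit of 2 lines alone. In a fit of 2 lines alone all 3 lost their call in PC3-ML, and RGS4 in PC3-N(PDGFRα). Each of the other genes left the overlap in at least 1 setting. With a replicate block those that left were CXCL1, FAM111B, MAP4K5 and TRNT1. PC3-ML and PC3-N(PDGFRα) alone shared 26 higher and 11 lower genes, with 0.610 and 0.163 for independent lists and at most 0 in the simulations.

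**Figure D4:**
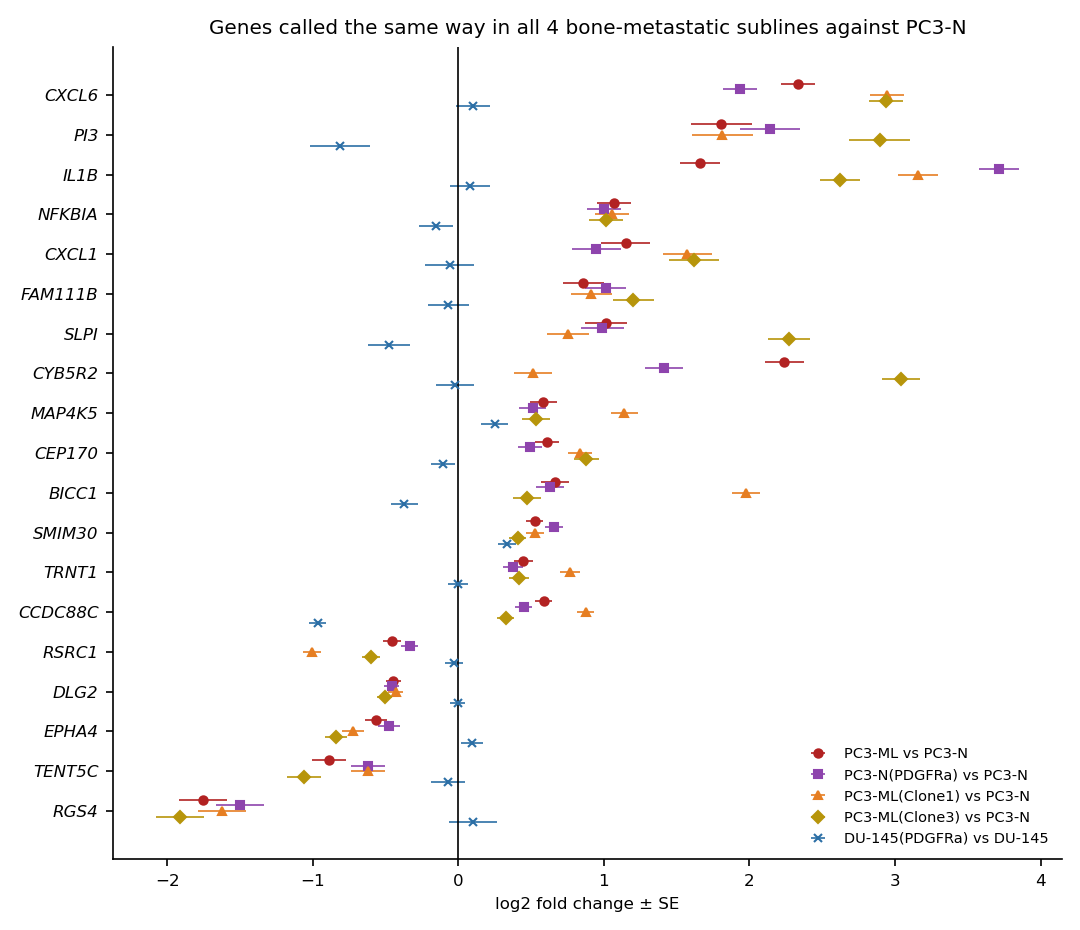
Log2 fold change ± SE of the 19 genes called in the same direction in all 4 bone-metastatic lines against PC3-N, with the effect of PDGFRα overexpression in DU-145 beside them. IL1B lies between 1.66 and 3.72 in the 4 lines and at 0.08 in DU-145.

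When the 4 bone-metastatic lines were set against the 3 others on line means, limma called 0 of 18372 genes, with a smallest adjusted p of 0.405 and 2250 genes at an unadjusted p under 0.05. The genes of smallest p that were higher in bone-metastatic lines were CXCL6 (log2 difference 3.00, SE 0.31), the chemokine CXCL1 (1.46), EMP2 (0.64), the proteasome gene PSMD12 (0.40) and the nuclear transport GTPase gene RAN (0.36). Those lower were RBPMS (−0.60), H2BC21 (−0.51), C8orf58 (−0.30), SEMA4G (−0.26) and SPATA41 (−0.20), all with an adjusted p of 0.405. IL1B differed by 3.79 with the same adjusted p, and PDGFRA by 1.05 (SE 1.16, adjusted p = 0.684). In every bone-metastatic line 663 genes lay above all 3 others and 1052 below, 9.33% of genes. Chance gives 5.71% for 7 exchangeable lines and more with both DU-145 lines among the 3, so no excess is shown. In the IL-1 and NF-kB list 0 of 21 were called, 7 had an unadjusted p under 0.05, and 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.282). Both DU-145 lines are labelled as not bone metastatic, so background and label overlap. With background as a covariate 0 genes were called (654 at an unadjusted p under 0.05), and 0 in PC3 lines alone (622). With all 14 arrays and the line as a random block limma called 77, among them CXCL6 (adjusted p = 5.8e-05), IL1B (0.0027) and CXCL1 (0.0052). That fit takes 1 consensus correlation between passages, 0.447, for all genes. On line means without PC3-N 2520 were called, which leaves PC3 against DU-145 lines.

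PC3-N and DU-145, both unmodified and labelled as not bone metastatic, set the scale of a difference between cell lines. The largest measured rises in PC3-N were in CALB1, a calcium-binding protein (log2 difference 6.27, SE 0.11, adjusted p = 1.3e-09), then H4C5, a histone gene (5.67), the activin antagonist FST (5.25), the cadherin CDH11 (4.97) and ADGRF1 (4.70). The ubiquitin hydrolase UCHL1 was among the largest measured falls (−5.96), with LY6K (−4.28), COXFA4L3 (−4.05), STAT3, a transcription factor downstream of interleukin-6 (−3.78, 25.5 against 355.2), and LMO3 (−3.69). Apart from LY6K, the lower level of each of these 10 genes was 29.0 or less, near the floor, so the differences are low estimates and not ranked. PDGFRA (1.99), IL1B (1.54) and CXCL6 (0.74) were higher in PC3-N. Mesenchymal markers were higher in PC3-N (adjusted p = 0.00349, and adjusted p = 0.294 with an estimated correlation): 6 of 14 rose, the same 6 over the list alone, with CDH11, N-cadherin CDH2 (4.33), FN1 (3.28) and S100A4 (2.88). The epithelial E-cadherin CDH1 was at −2.18 and EPCAM at −1.48; of 15 epithelial markers 2 were higher and 4 lower. The IL-1 and NF-kB list was lower in PC3-N (adjusted p = 0.0212, and adjusted p = 0.686 with an estimated correlation): 2 of 21 were higher, 7 lower, 2 and 8 over the list alone, with CXCL2 at −2.19, NFKBIA at −1.91 and IL6 at −1.67.

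Cell cycle genes were lower in PC3-N than in DU-145 (adjusted p = 0.00130, and adjusted p = 0.592 with an estimated correlation; 1 of 17 higher and 9 lower, 2 and 10 over the list alone), with TOP2A at −1.12 and MKI67 at −1.06. MAPK output genes were higher (adjusted p = 0.0279, and adjusted p = 0.527 with an estimated correlation; 8 of 19 higher and 2 lower, 12 and 2 over the list alone), with SPRED1 at 1.73 and SPRY4 at 1.52. In all 4309 genes were called, 2488 higher and 1821 lower (2092 and 2207 with quantile normalization, which turns the balance), 799 of them at least 2-fold, and between 3040 and 3934 without any 1 array. All 10 leading genes kept their call without any 1 array, as did the list members named here for this comparison.

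Camera called 21 of the 180 pairs of list and comparison, fry 29, and camera with an estimated correlation 0. Fry called 15 of the 21. It did not call the lists of hypoxia, amino acid and ER stress, and cell cycle genes where its adjusted p is given above. In the 21, the median, the mean and the test had the same sign. The other 10 lists passed in no comparison: their smallest adjusted p was 0.0505 for interferon-stimulated genes, 0.0610 for matrix proteases, 0.0914 for PDGF ligands and receptors, 0.179 for cholesterol synthesis, 0.275 for neuroendocrine markers and 0.292 for bone and osteomimicry genes. It was 0.487 for leukocyte and endothelial markers, 0.510 for fibroblast and stromal markers, 0.527 for basal epithelial markers and 0.660 for the androgen receptor program. Single members were called all the same, such as IFIH1, a sensor of viral RNA (1.31 in Clone 1 against PC3-N), IFI44L (1.25 in Clone 3 against PC3-N), and the homeobox gene HOXB13 (2.55 in PC3-N against DU-145).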

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

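The tests of the receptor level reached in each background and of the spread between passages were chosen only after the results were seen.

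The measured effect of PDGFRα overexpression differed between the 2 backgrounds in 98 genes, by limma's test of the difference itself. The log2 differences, PC3-N minus DU-145, were 3.64 for IL1B, 2.96 for PI3, 2.33 for GALC, 2.27 for MLLT11, 2.17 for ESM1 and 1.83 for CXCL6. They were −1.91 for CCNA1, −1.88 for TSPAN8, −1.67 for PLK2, −1.62 for PLAT and −1.60 for RGS4. In DU-145 lines IL1B, ESM1, CXCL6, CCNA1, TSPAN8, PLAT and RGS4 lay near the floor (24.3 to 43.9), so the size of their differences is uncertain. The IL-1 and NF-kB list had a mean difference of 0.64. The count of 98 was 39 and 153 without PC3-N replicates 1 and 2, 26 and 44 without PC3-N(PDGFRα) replicates 1 and 2, 58 and 249 without DU-145 replicates 1 and 2, and 63 and 45 without DU-145 (PDGFRα) replicates 1 and 2. MLLT11, PLAT and RGS4 lost their call without 1 or more of these arrays (adjusted p up to 0.0964).

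Fewer genes were called for the overexpression in DU-145 (57) than in PC3-N (405), but the order depends on single arrays: DU-145 gave 418 without DU-145 replicate 2, and PC3-N 118 without PC3-N replicate 1 and 71 and 158 without PC3-N(PDGFRα) replicates 1 and 2. A smaller effect in DU-145 cannot be told apart from a larger spread between its passages, since 12 genes had line means 2-fold apart in DU-145 and 53 in PC3-N, but 53 in both without DU-145 replicate 2. A candidate explanation is the lower receptor transcript level reached in DU-145, since PDGFRA intensity was 7.52 times as high in PC3-N(PDGFRα) as in DU-145 (PDGFRα). The latter, at 110.9, only reached the level of unmodified PC3-N, at 106.4. A difference between the backgrounds in what follows the receptor stays open and was not tested, since no DU-145 line had the higher level.

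Among the 4 bone-metastatic lines, 1 line stood far from the other 3 in 4 of 30 named genes, with a gap to the nearest line of 0.870 of the range for BICC1 in Clone 1, 0.882 for MAP4K5 in Clone 1, 0.928 for RBPMS in PC3-N(PDGFRα) and 0.830 for SLPI in Clone 3. Chance gives about 1 in 20 such gaps.

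The 9538 probe sets that carried no gene symbol or several were not used in the comparisons, and limma called some of them. For PC3-N the numbers were 8 against PC3-ML, 4 against PC3-N(PDGFRα), 285 against Clone 1, 117 against Clone 3 and 604 against DU-145. They were 411 for Clone 1 and 170 for Clone 3 against PC3-ML, and 11 for DU-145 (PDGFRα) against DU-145.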

How the results depend on the processing

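The fit without DU-145 replicate 1 was chosen only after the data were seen for comparisons that DU-145 is no part of, and the other alternatives before. Over all alternatives 0 of the 360 called results of single genes changed sign, and uncalled results were not checked for this. Only quantile normalization, median centring and leaving out an array could change a sign, as the other settings keep the log2 changes as they are. Leaving out an array could not do so for genes named because their arrays did not overlap. The 0 is therefore weak evidence of stability. The 360 called results of single genes stayed called in 2209 of 2466 values under other settings and in 1331 of 1754 with 1 array left out, and 230 uncalled results became called in 76 of 2674. A single array left in a line was assumed to vary like the other lines. Counts moved by over 1.5 times as follows; apart from a minimum fold, a smaller set of arrays or fewer genes tested, the cause was not tested.

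With a replicate block, PC3-ML against PC3-N gave 42 genes and DU-145 (PDGFRα) against DU-145 gave 10. Over 21 pairs of lines, the differences between replicates correlated at r of −0.199 to 0.245 (median 0.036). PC3-N, PC3-N(PDGFRα) and DU-145 went the same way (0.111 to 0.245) and PC3-ML the opposite way to these 3 (−0.199 to −0.163). Integrins in Clone 1 against PC3-ML then had an adjusted p of 0.0600. With a filter on dim probes PC3-ML against PC3-N gave 103, and with an intensity trend DU-145 (PDGFRα) against DU-145 gave 100. With a fit of the 2 lines alone, which has fewer arrays to estimate the spread, counts were 1 for PC3-ML against PC3-N, 6 for PC3-N(PDGFRα) against PC3-N, 0 for DU-145 (PDGFRα) against DU-145 (limma, 2386 at an unadjusted p under 0.05 with all arrays), 484 for Clone 3 against PC3-N, 944 for Clone 3 against PC3-ML and 2474 for PC3-N against DU-145. The difference of the overexpression effects has no such fit. A change of at least 2-fold was met by 16 genes for PC3-ML against PC3-N, 44 for PC3-N(PDGFRα) against PC3-N, 6 for DU-145 (PDGFRα) against DU-145, 214 and 88 for Clone 1 and Clone 3 against PC3-N, and 230 and 115 for Clone 1 and Clone 3 against PC3-ML. It was met by 799 for PC3-N against DU-145, 34 for the difference of effects and 5 of the genes shared by all 4 lines. For the bone-metastatic lines, the line as a random block gave 77 genes (consensus correlation 0.447). Camera with an estimated correlation called 0 of 180 lists, against 21 with the preset one and 29 by fry, 15 of them among the 21.

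With 1 array left out, the counts ranged from 12 to 170 for PC3-ML against PC3-N (lowest and highest without PC3-N replicates 1 and 2), 71 to 500 for PC3-N(PDGFRα) against PC3-N (without PC3-N(PDGFRα) replicate 1 and DU-145 replicate 1) and 15 to 418 for DU-145 (PDGFRα) against DU-145 (without DU-145 (PDGFRα) replicate 2 and DU-145 replicate 2). They ranged from 1325 to 2696 for Clone 1 and 604 to 1542 for Clone 3 against PC3-N, each highest without DU-145 replicate 1 and lowest without replicate 2 of the clone. Against PC3-ML they ranged from 1213 to 2791 for Clone 1 and 431 to 1718 for Clone 3, lowest without PC3-ML replicate 1. For PC3-N against DU-145 they ranged from 3040 to 3934, for the difference of effects from 26 to 249 (without PC3-N(PDGFRα) replicate 1 and DU-145 replicate 2), and for genes shared by all 4 lines from 4 to 57 (without PC3-N replicates 1 and 2). For bone-metastatic lines they were 0 to 2520, the latter without the line PC3-N. Signal over background limits dim genes: array medians of 29.9 to 31.6 lie close to the lowest intensity, 18.5, so changes among dim genes are compressed.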

Other observations

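The tests of single PC3-N arrays, of all 7 passage axes, of the lines of PC3 background, of spread and of other splits by unadjusted p were chosen only after the results were seen, that of Clone 1 against Clone 3 after the data were seen but before its own result, and those of the first passage axis and of other splits by called genes before.

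Of the 14 measured members of the matrix protease list, 4 were called in each single-cell clone against PC3-N, 1 higher and 3 lower, and the list did not pass in either (smallest adjusted p over all comparisons 0.0610). TIMP1, an inhibitor of metalloproteinases, was higher than in PC3-N in Clone 1 (log2 change 1.01) and Clone 3 (0.78), and higher than in PC3-ML in both (1.55 and 1.32). Its relatives went the other way against PC3-N: TIMP2 fell in Clone 1 (−0.85) and Clone 3 (−1.24), as did TIMP3 (−0.81 and −0.48), and PLAT fell in both (−3.45 and −1.01). PLAT and TIMP3 were lower in PC3-N(PDGFRα) too (−1.45 and −0.78), so their falls were not limited to the clones, while TIMP3 rose in PC3-ML (1.75). Against PC3-N, TIMP1 lost its call in Clone 1 without PC3-N replicate 1 or Clone 1 replicate 2 (adjusted p up to 0.0812), and in Clone 3 without any of the 4 arrays (up to 0.208). In Clone 3, TIMP3 lost it without either PC3-N array or Clone 3 replicate 2, PLAT without PC3-N replicate 1 or Clone 3 replicate 2 (both under 0.208), and TIMP1 against PC3-ML without PC3-ML replicate 1 (0.0510). A second TIMP3 probe set gave −0.33 in Clone 1 and −0.16 in Clone 3 against PC3-N, the latter not called. It gave −0.22 in PC3-N(PDGFRα) and 0.37 in PC3-ML, neither called, so the TIMP3 changes in these lines rest on 1 probe set.

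IL1B, CXCL6, CXCL1 and NFKBIA, of the IL-1 and NF-kB list, were higher in all 4 bone-metastatic lines than in PC3-N. With a replicate block CXCL1 lost its call in PC3-ML and so was not among the shared genes. Interest in IL1B and CXCL6 came from the study's publication. An out-of-place PC3-N array is argued against for IL1B and CXCL6, which stayed called in 16 of 16 comparisons with either PC3-N array left out, with a smallest log2 change of 1.451. The first axis of the differences between passages held 27.6% of their variance, with its largest loading in DU-145. It accounted for a median share of 0.002965 of the changes of the 4 genes (highest 0.106), and all 7 axes together for 0.1976 at most. The weights of the axes were fitted on other genes, so these shares argue only against a change along these axes. A passage effect on single genes, or a culture difference between PC3-N and the other lines, is not covered and stays open. For CXCL1 and NFKBIA an out-of-place PC3-N array stays open: their changes kept at least 0.8623 of their size, but 13 of 16 stayed called (adjusted p up to 0.201, without PC3-N replicate 1 for PC3-ML), and part of the overlap may come from the PC3-N arrays that all 4 comparisons share. Bone-metastatic potential of the line cannot be told apart from other properties of PC3-N, because the design has 1 line of PC3 background labelled as not bone metastatic.

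The clones differed from PC3-ML in more genes (2533 and 1489) than PC3-ML did from PC3-N (64); without PC3-ML replicate 1 the counts were 1213, 431 and 15, and the last was 12 and 170 without PC3-N replicates 1 and 2. A batch shared by the clones as the whole cause is argued against, since 1925 genes were called between Clone 1 and Clone 3 themselves. A smaller spread between their passages is argued against too, since it would not raise the number of line means 2-fold apart, which was 121 in Clone 3 and 232 in Clone 1 against 34 for PC3-ML and PC3-N, and over 1.5 times as high in both with any 1 array left out (nearest without PC3-N replicate 2, 121 against 78). Of the genes called in both clones, 465 were higher and 239 lower in both and 62 went opposite ways, where independent lists would share 86.2 and 25.4. In 50 simulations of clones with no effect at all, at most 0 were shared, which was bound to follow with no gene changed. Part of this overlap may come from the PC3-ML arrays that both comparisons share, and single-cell derivation or a partly shared batch stay open too, which the 1925 genes do not settle.

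For the comparison of the 4 bone-metastatic lines with the 3 others, 0 genes were called, so all 35 splits of the 7 lines into 4 and 3 had as many by necessity (highest other split 3), which says nothing about chance. At an unadjusted p under 0.05 the real split had 2250 genes, and 5 of the 35 splits had as many, the real one included. In each of these 5, both DU-145 lines were in the group of 3 with 1 PC3 line. Those beside the real one had 2280, 2745, 2984 and 3183 genes, so the real split had the fewest of the 5. By this count the genes follow PC3 against DU-145 background, no excess is shown for the label, and chance cannot be excluded.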
